A study of Mus musculus with 5 samples.

How the data were processed

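eCLIP libraries were made from GC-2spd(ts) cells with antibodies against PABPC1 and CCT3, and input libraries were prepared alongside from the same lysates, per the labels' protocols. The 5 samples fell into 4 groups by their titles. The submitters' processing notes name bcl2fastq 2.20 and the build mm10. The aligner, the peak caller, the annotation tool and the treatment of duplicate reads are not given in the sources used here. Each of the 3 tables is the authors' list for 1 sample, with a position, a fold and a p per peak.

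The deposited −log10 p values are those of the authors and stop at 400, reached by 677 PABPC1, 56 CCT3 and 256 CCT3-2 peaks. The deposited log2 fold values are those of the authors. The header of the CCT3 table names a log2 fold, taken here as the immunoprecipitation over input. The columns of the PABPC1 and CCT3-2 tables are unnamed and were read as the same quantities from their ranges. All peaks of the PABPC1 and CCT3 lists had both values at 3 or more, whereas 83.7% of CCT3-2 peaks did. Both values were used to describe, rank or filter peaks within a list. The log2 folds were also compared across lists as rank correlations, as a median difference between the CCT3 lists and to rank shared genes by the smaller fold, and none of these is a test of a difference between samples. The PABPC1 and CCT3-2 tables give a strand and the CCT3 table does not, so the same-strand overlap chosen before the data were examined was replaced by overlap regardless of strand.

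The gene named in the tables is that of the nearest transcription start, and its RefSeq span held the peak for 68.5% of PABPC1, 82.2% of CCT3 and 82.4% of CCT3-2 peaks. After this was seen, peaks were assigned to the RefSeq gene (GRCm38.p6, the same build) whose span holds them. A small RNA gene was taken first, then the gene ID in the peak's annotation, then the single gene at that position, then the listed gene among several. This assigned 97.9%, 98.2% and 98.0% of peaks. Listed transcript coordinates lay on or within 100 bases of the RefSeq span of the same gene ID for 99.8% of peaks in each list. Tug1 peaks were counted by listed name, with position as the alternative.

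Genomic features were taken from the deposited annotation. Overlaps used bedtools 2.31.1 with a minimum of 1 base. Random overlap came from 1000 seeded placements of each CCT3 peak anywhere in the span of its gene, introns included, since exon coordinates were not used here. Shares were given Wilson 95% intervals, and differences of shares Newcombe intervals, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The median highest fold of a gene list with at least 3 members in a peak list was set against 10000 random lists matched on peaks per gene in 5 groups. No p-value across genes or conditions was computed, since PABPC1 has 1 sample and the 2 CCT3 samples carry the same library name. Tested on simulated data, all 200 overlaps put into 10843 CCT3 peaks were found. Each was placed on a PABPC1 peak, so this checks the counting and not the ratio to random placements. Of 100 lists of 20 genes raised by 1 log2 unit among 2111 CCT3 genes, 100 lay above percentile 95, as did 2 of 100 unraised lists. The CCT3 gene lists given a percentile had only 4 to 8 genes with a peak, a size at which detection was not tested.

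Gene lists, cell type markers and the rule for named genes were fixed before the data were examined. The rule names Tug1, Pabpc1 and Cct3, the genes of the 8 highest folds and the 5 with most peaks per protein, the 5 shared genes with the highest smaller fold, and up to 4 members per list. Genes named outside it, such as Rps15a, Sox9, the cell cycle genes with a CCT3 peak and examples of overlapping peaks, were chosen after their values were seen. The alternative settings chosen before the data were examined were a log2 fold of at least 4 with a −log10 p of at least 5, merging within 10 bases, covered bases, 50% reciprocal overlap, protein-coding genes, exonic peaks, Tug1 by position, and the CCT3-2 list in place of CCT3. Those chosen after seeing the data were listed gene names, peaks beyond 1000 bases of the start, same-strand overlap with the CCT3-2 list, shifts of 1 to 5 kb, the CCT3-2 list at the threshold of the others, the PABPC1 list without opposite-strand peaks, and, for the distance to the 3′ end, a stricter threshold, the CCT3-2 list, and a gene strand taken from most of a gene's peaks where the tables give none. Distances used exonic peaks, small RNA genes left out, in genes whose strand the tables give. Sequence content of peaks was not analysed here, as no genome sequence was used.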

Results

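The series profiled the RNA bound by PABPC1, the cytoplasmic poly(A)-binding protein, and by CCT3, a subunit of the TRiC/CCT chaperonin, in GC-2spd(ts), a mouse cell line labelled as spermatocyte cells. The assay was eCLIP, in which RNA crosslinked to a protein is immunoprecipitated, trimmed with RNase and sequenced beside an input library from the same lysate. The 5 samples comprised 1 PABPC1 immunoprecipitation, 1 PABPC1 input, 2 samples of CCT3 immunoprecipitation and 1 CCT3 input. The title of the series names the long noncoding RNA Tug1 as the RNA of interest. The analysis used 3 peak lists, called here PABPC1, CCT3 and CCT3-2, which held 14092, 10916 and 18650 peaks. Read totals per library were not used here, so the depth behind each peak is unknown. There was 1 list per protein apart from CCT3-2, whose labels carry the same library name as CCT3, and no difference between the proteins has a replicate check. The fold over input and the p of each peak are the authors' own values. Intervals on shares are Wilson 95% intervals, which cover counting error only. The use of molecular identifiers is not given in the sources used here, PCR reads without them are not independent molecules, and neighbouring peaks are not independent either.

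PABPC1 peaks lay mostly in 3′ UTRs, and CCT3 peaks mostly in other exons and in introns. The deposited annotation placed 79.9% of PABPC1 peaks in 3′ UTRs (95% interval 79.3 to 80.6%, 11263 of 14092), against 18.0% of CCT3 peaks (17.3 to 18.8%, 1969 of 10916), a difference of 61.9 percentage points (60.9 to 62.9). CCT3 peaks fell in other exons in 47.9% of cases (47.0 to 48.9%) and in introns in 29.6% (28.8 to 30.5%). For PABPC1 the share in other exons was 5.36% and the share in introns 1.09%. The CCT3-2 list had 38.6% of peaks in other exons, 27.6% in introns and 16.5% in 3′ UTRs. The promoter class is not comparable between the tables, at 13.2% of PABPC1, 0.925% of CCT3 and 16.2% of CCT3-2 peaks. Among peaks more than 1000 bases from the listed transcription start, 92.1% of PABPC1 and 19.6% of CCT3 peaks were in 3′ UTRs.

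**Figure D1:**
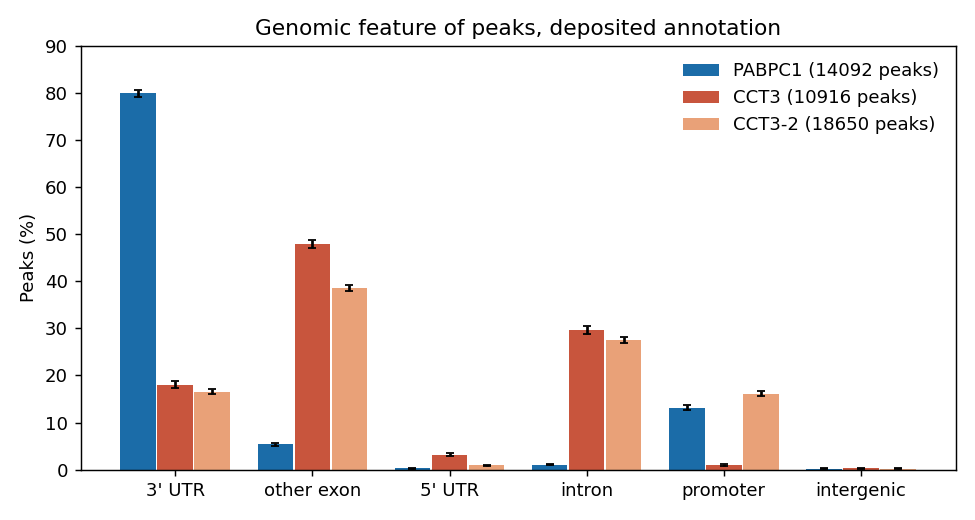
Share of peaks (%) in each genomic feature of the deposited annotation for the PABPC1, CCT3 and CCT3-2 lists, with Wilson 95% intervals as error bars. The PABPC1 bar for 3′ UTRs stands at 79.9%, and the CCT3 bars for other exons and introns at 47.9% and 29.6%.

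The position of exonic peaks along their genes differed in the same way. Distances were measured for exonic peaks in genes whose strand the tables give, 9237 of 12056 for PABPC1 (76.6%) and 6709 of 7545 for CCT3 (88.9%). Of the 9237 PABPC1 peaks, 48.3% (47.3 to 49.3%) had their midpoint within 500 bases of the 3′ end of the RefSeq gene span and 16.6% (15.8 to 17.3%) within 100 bases. Of the 6709 CCT3 peaks, 2.07% (1.76 to 2.44%) were within 500 bases and 0.134% (0.0706 to 0.255%) within 100 bases. The median distance was 540 bases for PABPC1 and 6928 bases for CCT3. With gene strand also taken from the peaks, which brought in 97.9% and 98.1% of exonic peaks and was chosen after seeing the data, 49.8% and 2.19% were within 500 bases. Distances are to the end of the gene span along the genome, introns included, not to the end of each transcript.

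**Figure D2:**
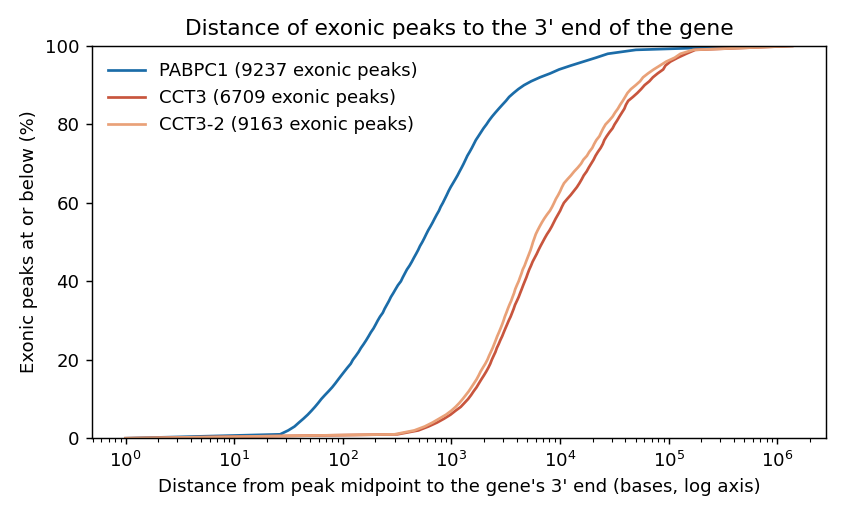
Cumulative share (%) of exonic peaks by distance in bases, on a log axis, from the peak midpoint to the 3′ end of the gene, with 1 line per list. The PABPC1 line reaches 48.3% at 500 bases, where the CCT3 line is at 2.07%.

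Tug1 carried many CCT3 peaks and a single PABPC1 peak. Tug1 (gene ID 544752) is transcribed from the minus strand of chromosome 11 at 3639785 to 3648814 in mm10. The CCT3 list named Tug1 for 46 peaks, of which 44 lay within this span, covering 2433 of its 9030 bases (26.9%). These 44 peaks, all annotated as exonic, had a median log2 fold of 4.61. The highest, at 3645025 to 3645143, had a log2 fold of 7.22 and a −log10 p of 62.2. By number of peaks Tug1 ranked 3 among 2111 genes of the CCT3 list, after Dst with 69 peaks and Wwox with 52. By its highest fold it ranked 9. The CCT3-2 list named Tug1 for 75 peaks, 73 of them within the span, covering 30.1% of it.

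The PABPC1 peak in Tug1 lay at 3644164 to 3644194 in an exon, with a log2 fold of 3.77 and a −log10 p of 3.56. A larger −log10 p was listed for 95.2% of PABPC1 peaks and a larger fold for 67.4%. The peak was absent at the stricter threshold of a log2 fold of 4 and a −log10 p of 5, at which 31 CCT3 peaks remained in Tug1. No CCT3 peak overlapped it, the nearest lying 216 bases away, and the nearest CCT3-2 peak lay 209 bases away.

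**Figure D3:**
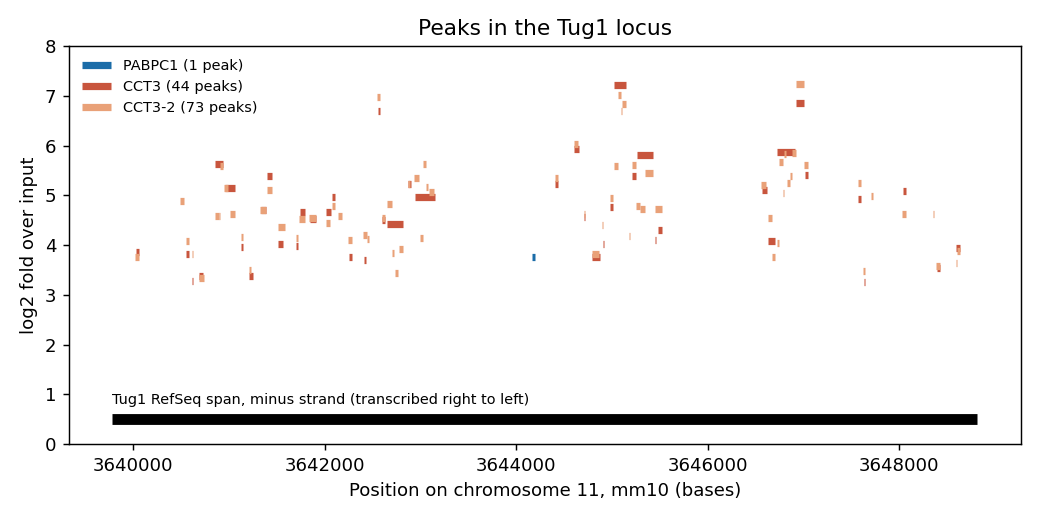
Peaks in the Tug1 locus on chromosome 11 (mm10, position in bases), drawn to scale as bars at their log2 fold over input for the PABPC1, CCT3 and CCT3-2 lists, with the RefSeq span in black. The single PABPC1 peak at a log2 fold of 3.77 lies in a gap between the 44 CCT3 peaks.

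Genes encoding the protein synthesis and folding machinery were reached more often by PABPC1 peaks than by CCT3 peaks. PABPC1 peaks lay in 5413 genes and CCT3 peaks in 2111, among them 5267 and 2017 of 21887 protein-coding genes. Over all 761 genes of the fixed lists, 34.6% had a PABPC1 peak and 4.86% a CCT3 peak, so the direction is not particular to this machinery. Of 40 translation factor genes, 25 had a PABPC1 peak, 2 a CCT3 peak and 5 a CCT3-2 peak, with PABPC1 log2 folds of 9.38 for Eif4g3, 6.76 for Eif3a and 6.65 for Eif1. Of 86 cytoplasmic ribosomal protein genes, 48 had a PABPC1 peak and 1 (Rps15a) a CCT3 peak. The median highest fold of the 48 was 3.76, lower than in any of 10000 random lists matched on peaks per gene. Such a percentile was computed for 16 lists in PABPC1 and 5 in CCT3, and the other PABPC1 lists ranged from 5.90 to 99.9. PABPC1 peaks lay in 7 of the 8 TRiC/CCT subunit genes, led by Cct2 at 9.33, Cct8 at 7.87 and Cct4 at 6.68, while no subunit gene had a CCT3 peak. Cct3 itself had 1 PABPC1 peak at a log2 fold of 3.32. Of 25 heat shock and co-chaperone genes, 18 had a PABPC1 peak, among them Hspa5, the endoplasmic reticulum Hsp70, at 8.97 and Hsp90b1 with 22 peaks, and 2 had a CCT3 peak. Among 27 TRiC partners and substrates the counts were 16 and 1, with Pfdn2, a prefoldin subunit, at 7.27 in PABPC1.

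Genes for poly(A) tail and RNA-binding factors appeared in both lists. Of 31 poly(A) tail and deadenylation factor genes, 20 had a PABPC1 peak and 7 a CCT3 peak, 4 of them shared. Pabpc1 had 16 PABPC1 peaks with a highest log2 fold of 8.94 and no CCT3 peak. Pan3, a subunit of a deadenylase, had 6 CCT3 peaks up to 7.15 (11 in CCT3-2) and 1 PABPC1 peak at 4.00. Of 31 nuclear RNA-binding protein genes, 25 had a PABPC1 peak and 5 a CCT3 peak. The median highest PABPC1 fold of those 25 was 6.18, at percentile 99.9 of the random lists, with Hnrnpc at 7.39 and Elavl1 at 7.30. Hnrnpl had 21 CCT3 peaks with a log2 fold of up to 7.96, and 53 CCT3-2 peaks. Of 11 Polycomb repressive complex 2 genes, 10 had a PABPC1 peak, including Jarid2 at 6.67 and Suz12 at 5.65, and 2 a CCT3 peak.

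The counts for growth control genes were 18 of 30 cell cycle genes in PABPC1, with Mcm5 at 6.72, and 4 in CCT3 (Cenpf, Cenpe, Myc and Mki67). The median highest CCT3 fold of those 4 was 4.21, at percentile 1.56 of the random lists, the lowest of the 5 CCT3 lists, whose highest was 81.2 for poly(A) tail factors. Of 24 p53 target and apoptosis genes, 8 had a PABPC1 peak, Mdm2 reaching 8.26, and 4 a CCT3 peak, Bcl2 carrying 16 with a log2 fold of up to 4.96. Long noncoding RNAs were the list with more genes in CCT3 than in PABPC1, at 8 and 5 of 36. The intervals of these shares overlap (11.7 to 38.1% and 6.08 to 28.7%), and CCT3-2 reached 7. Airn had 35 CCT3 peaks and Neat1 12, against 59 and 69 in CCT3-2, with no PABPC1 peak in either, whereas Epb41l4aos had 2 PABPC1 peaks up to 8.09 and no CCT3 peak. Replication-dependent histone genes, whose mRNAs typically lack a poly(A) tail, had a PABPC1 peak in 2 of 63 cases (H2bc21 and H2bc4) and no CCT3 peak. None of the 37 mitochondrially encoded genes and none of the 220 structural RNA genes had a peak in either list. Whether reads of such genes were removed before peak calling is not known here, so their absence is not shown to reflect binding.

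Markers of testicular cell types were frequent in the PABPC1 list. Of 41 meiotic spermatocyte markers, 26 had a PABPC1 peak (63.4%, 48.1 to 76.4%), including Dazl at a log2 fold of 7.53, Stra8 at 7.47, Sycp1 at 6.52 and Piwil1 with 18 peaks. Of 15 spermatid markers, 12 had one, with the protamine gene Prm1 at 8.43 and the transition protein gene Tnp2 at 5.54. Leydig cell markers had a PABPC1 peak in 5 of 7 cases, with Insl3 carrying 22 peaks up to 7.71 and Cyp11a1 6 peaks up to 5.57. The Insl3 peaks lie where gene spans overlap and follow the listed name. Sertoli cell markers had one in 7 of 11 cases, led by Clu at 5.35 and Cldn11 at 5.26, and fibroblast markers in 12 of 19, led by Sparc at 6.34 and Timp3 at 6.19. In the CCT3 list the counts were 0, 0, 0, 1 (Sox9) and 0, and in CCT3-2 they were 1, 1, 0, 1 and 0. In the same order, the median highest PABPC1 folds lay at percentiles 8.1, 65.9, 16.7, 6.4 and 36.2 of the random lists. These marker genes come from the same list as every PABPC1 count given here. A difference in source RNA between the PABPC1 and CCT3 libraries was not excluded for any comparison of the proteins, shared genes and overlapping peaks included.

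**Figure D4:**
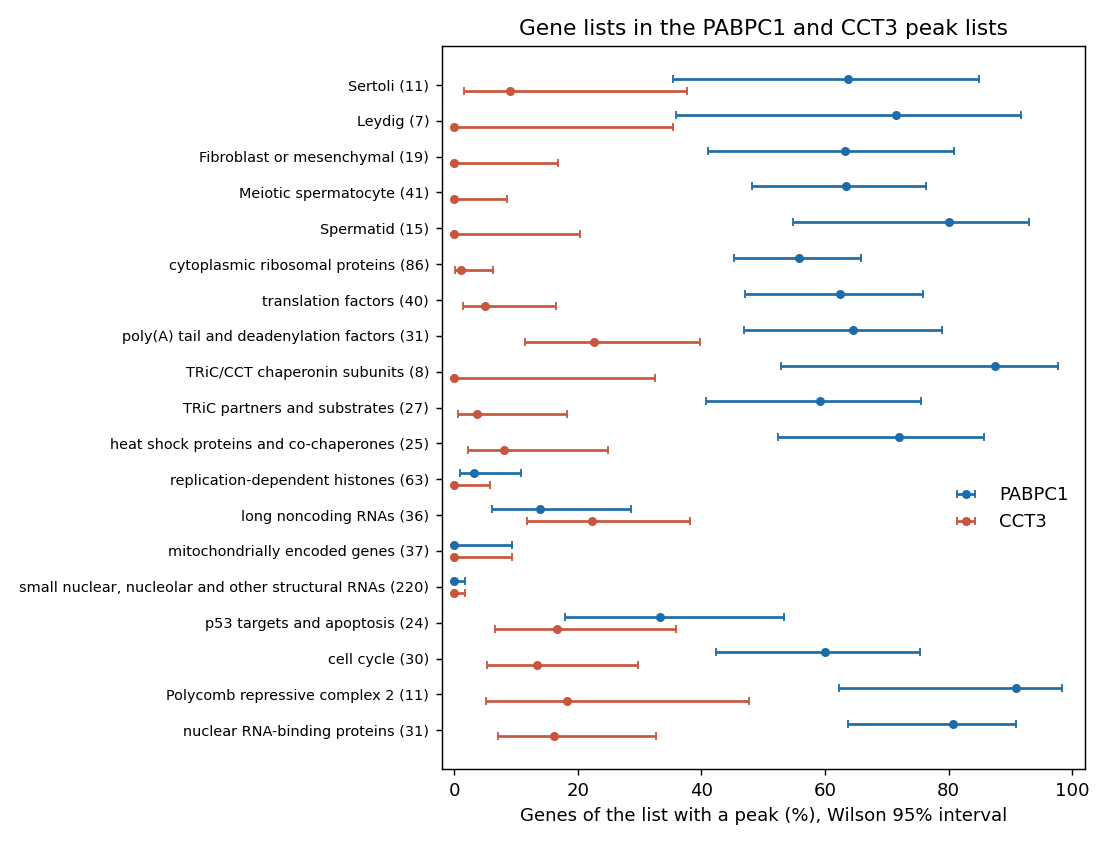
Share (%) of the genes of each list with at least 1 peak in PABPC1 and in CCT3, with Wilson 95% intervals as bars and the number of genes in brackets. PABPC1 reaches 26 of 41 meiotic spermatocyte markers and CCT3 none of them.

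The genes with the highest folds differed between the proteins. In PABPC1 they were Mrto4 at a log2 fold of 11.94, the microRNA gene Mir423 at 11.43, Ccp110 at 9.83, Vps18 at 9.73, Abi3 at 9.66, Tex30 at 9.49 and Copa at 9.48, while 1 of the 8 highest peaks had no assigned gene. The highest Abi3 peak and 3 more of its 7 lie where gene spans overlap, and 1 is on the opposite strand. The highest Vps18 and Copa peaks were intronic, as were all 3 Vps18 peaks and 3 of 9 Copa peaks. Some of the highest peaks were only a few bases wide, such as 77078122 to 77078123 in Mir423 and 95830960 to 95830963 in Abi3. Slc2a3, a glucose transporter gene, had the most PABPC1 peaks at 31, all in its 3′ UTR, followed by Hnrnpa2b1 with 23. In CCT3 the highest were Lrp2 at 8.67 with 1 intronic peak, Hnrnpl, Nedd4 at 7.81, Brip1os at 7.76, Arid5b at 7.56, Trim30d at 7.48, Rbm12b2 at 7.43 and Zfp101 at 7.25. Dst, a cytoskeletal linker gene, had 58 of its 69 CCT3 peaks in other exons, 3 in the 3′ UTR and 0 in introns, whereas all 52 in Wwox were intronic. Zfp292 had 41 CCT3 peaks and Amer1 38. Peak numbers per gene depend on the CCT3 list used, with 103 CCT3-2 peaks in Dst, 82 in Wwox, 70 in Zfp292 and 62 in Amer1.

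The proteins shared 696 genes, which were 33.0% of CCT3 genes (31.0 to 35.0%) and 12.9% of PABPC1 genes, with a Jaccard index of 0.102. Independent lists of these sizes among 39334 annotated genes would share 290.5, or 485.4 among protein-coding genes alone, where 693 were shared. Expression was not measured, and counting genes that are not expressed lowers both references. They are loose and do not show sharing beyond what expressed genes alone would give. Across the shared genes, which are not independent replicates, the highest folds had a Spearman correlation of 0.0393. The highest smaller folds belonged to Nedd4, Hnrnpl, Zfp597, Orc3 and Mir423. In Nedd4, a ubiquitin ligase gene, all 11 PABPC1 peaks were in the 3′ UTR and none of the 13 CCT3 peaks. All 3 PABPC1 peaks assigned to Orc3 lie on the opposite strand, and the 3 PABPC1 peaks in Zfp597 lie where gene spans overlap. At the stricter threshold the proteins shared 206 genes, 18.6% of CCT3 genes (16.4 to 21.0%).

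Peaks of the proteins rarely overlapped. Of 10916 CCT3 peaks, 73 (0.669%, 0.532 to 0.840%) overlapped a PABPC1 peak by at least 1 base, in genes including Zfp597, Mir423, Hsp90aa1, Tuba4a and Cenpe. Placing each CCT3 peak at random within its own gene 1000 times gave a mean of 33.8 overlaps (range 14 to 53). The observed count was 2.16 times that mean, 2.33 times the mean after shifts of 1 to 5 kb, and 3.02 times with the CCT3-2 list (172 against 56.9). At the stricter threshold 6 peaks overlapped, against a mean of 7.76 (range 1 to 18). The placements include introns, where 1.09% of PABPC1 peaks lie, so their means are low for lists that both favour exons and the ratios do not show overlap beyond shared exons. The first CCT3 table carries no strand, and strand was ignored.

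The CCT3 and CCT3-2 lists shared most genes but few exact peak positions. Of CCT3 peaks 89.9% overlapped a CCT3-2 peak, and 64.3% of CCT3-2 peaks overlapped a CCT3 peak. They shared 2012 genes, among them Tug1, Hnrnpl and Airn. These were 95.3% of the 2111 genes of the CCT3 list, whereas the CCT3-2 list held 2716 genes. Only 37 peaks had identical coordinates, and none of these had the same fold within 1e-06. Across 9810 overlapping pairs the Spearman correlation of the log2 folds was 0.890, with a median difference of −0.05 for CCT3-2 minus CCT3. The pairs were chosen by overlap and the labels give 1 CCT3 input, and the correlation that these alone would give was not measured. With the shared library name these lists are not shown to be independent, and they were not averaged.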

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

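The strand column of the PABPC1 and CCT3-2 tables entered no main comparison, and it held peaks on the strand opposite to their assigned gene. There were 308 such peaks among 10875 PABPC1 peaks with a known gene strand (2.83%) and 499 among 16731 CCT3-2 peaks (2.98%). The 3 PABPC1 peaks assigned to Orc3 were among them.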

How the results depend on the processing

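The ratio of the peak overlap to random placements fell from above 1 (2.16) to below 1 (0.773) at the stricter threshold, and was 3.02 with the CCT3-2 list and 2.33 with shifts of 1 to 5 kb. Of 59 alternative values for 18 results 27 stayed within the interval of the main share or within 1.5 times the main count. No paired analysis was possible because no result came from a test across samples. At the stricter threshold the PABPC1 and CCT3 lists held 6974 and 4578 peaks, the PABPC1 share in 3′ UTRs was 85.9%, and CCT3 shares were 45.8% in other exons, 34.3% in introns and 15.6% in 3′ UTRs. There the peak overlap was 0.131%, shared genes 206, agreement of the CCT3 lists 82.4%, genes of the fixed lists 158 in PABPC1 and 14 in CCT3, those of the 4 testis lists 33 and 0, and PABPC1 peaks in Tug1 0, since fewer peaks pass. The share of PABPC1 exonic peaks within 500 bases of the 3′ end was then 51.8%, and 49.8% with gene strand also taken from the peaks, both chosen after seeing the data. By bases covered, the PABPC1 3′ UTR share was 80.7%. With the CCT3-2 list, shares were 38.6% in other exons, 27.6% in introns and 16.5% in 3′ UTRs, the peak overlap was 0.922%, Tug1 had 75 peaks and testis marker genes numbered 3. With 50% reciprocal overlap, 0.431% of CCT3 peaks overlapped PABPC1 and 77.9% overlapped CCT3-2. Of the alternatives chosen after seeing the data, peaks beyond 1000 bases of the start gave a PABPC1 3′ UTR share of 92.1% and CCT3 shares of 46.3%, 32.7% and 19.6% in other exons, introns and 3′ UTRs. There the CCT3-2 shares were 46.0%, 32.9% and 19.7%, so the lower CCT3-2 shares over all peaks came with its larger promoter class. Same-strand overlap with the CCT3-2 list was 0.895%, and listed gene names gave 2 testis marker genes in CCT3. The cause of the other differences was not tested except where the setting itself removes peaks. The planned same-strand overlap was not run on the CCT3 list, which has no strand. Read depth is unknown, so a gene without a peak is not shown to be unbound.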

Other observations

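Peaks lay in 35 microRNA genes in the PABPC1 list, 5 in CCT3 and 10 in CCT3-2, among 5413, 2111 and 2716 genes in all, and the difference was not tested. PABPC1 shared 1 of them (Mir423) with CCT3 and 4 (Mir423, Mir29a, Mir23a and Mir27a) with CCT3-2. The CCT3-2 count includes Mir10a and Mir5099, with highest log2 folds of 2.99 and 2.59. These lie below the log2 fold of 3 that every PABPC1 and CCT3 peak met. Besides Mir423, the highest PABPC1 folds were those of Mir143 at a log2 fold of 7.36, Mir27a at 7.20, Mir34c at 6.97 and Mir126a at 6.53. Mir34a, Mir34b and Mir449a, of the same family as Mir34c, were listed at 5.76, 4.86 and 4.78. In CCT3, Mir423 had a log2 fold of 6.32 and Mir6244 of 4.43, and in CCT3-2 Mir423 had the highest fold of the list at 8.94. These genes were looked at after their values were seen.

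All patterns below were noticed in the data. The tests of expression by the cell line and of zinc finger genes in PABPC1 were chosen only after the counts they rest on had been seen, and the raw counts of Malat1 peaks and of zinc finger genes in CCT3 were also known.

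The testis markers in the PABPC1 list span germ cells and somatic cells, with 50 of 74 genes of the 4 testis lists reached by PABPC1 and 1 by CCT3. Calls reaching genes of any tissue are argued against, since markers of liver, neuron, striated muscle, lymphocyte, epidermis and erythroid cells had a PABPC1 peak in 5.56% of 72 cases (95% interval 2.18 to 13.4%), against 51.9% (38.7 to 64.9%) of 52 further testis markers, none of them in the fixed lists. RNA of several testicular cell types in the PABPC1 library is a candidate explanation only. The upper bound of the other-tissue share was exceeded by 4 of 4 further lists. They had a peak in 5 of 12 spermatogonial, 14 of 23 spermatid, 6 of 9 Sertoli and 2 of 8 Leydig markers, the last too few to stand apart (7.15 to 59.1%). However, that bound lies below the 24.1% of protein-coding genes with a PABPC1 peak. This share is inside the spermatogonial and Leydig intervals and below the spermatid and Sertoli intervals. Expression by the cell line could exceed the bound too, so the test does not tell these explanations apart. Expression by the cell line itself stays open. CCT3 reached 3.85% of the further testis markers (1.06 to 13.0%) and 4.86% of all fixed-list genes, against 34.6% for PABPC1. The fixed lists include 220 structural RNA and 37 mitochondrially encoded genes without a peak in either list, which lowers both of these shares. Among 21887 protein-coding genes, CCT3 reached 2017 and PABPC1 5267. CCT3 thus reached fewer mRNAs than PABPC1, mostly outside 3′ UTRs, and cannot speak for mRNA levels. A difference in the cells, in the lysate or in a label was not tested and would bear on every comparison of PABPC1 with CCT3. Input libraries were not analysed here.

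Malat1, a nuclear long noncoding RNA, had 11 peaks in CCT3 and 117 in CCT3-2. The bases covered were 692 and 823, a ratio of 1.19, as splitting of the same stretch into several peaks would give. Totals were compared, not positions. Of the 117 CCT3-2 peaks, 19 overlapped no CCT3 peak, and splitting does not account for those. A looser threshold is argued against for the number of peaks only, since 99 of the CCT3-2 peaks met the threshold of the CCT3 list. For the excess of covered bases it stays open, since the threshold lowered the CCT3-2 value from 823 to 674 bases. Whether the 19 peaks without overlap met the threshold was not examined. The bound on covered bases set for the threshold test was met with the threshold (674 bases in CCT3-2, 692 in CCT3). It was already met without the threshold and decided nothing. The number of peaks was used in its place, with the raw counts already known. No biological explanation was tested.

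Zinc finger genes (symbols starting with Zfp, Zkscan or Zscan) were frequent in the CCT3 list, with a peak in 179 of 424 (42.2%, 37.6 to 47.0%), among them Zfp101 at 7.25, Zfp322a at 7.18 and Zfp451 at 6.90. Length of the gene span, introns included, is argued against, since 1000 random sets of protein-coding genes of the same span deciles reached at most 12.5%. Exon and transcript length were not matched in these sets, so room for peaks in long exons stays open. PABPC1 reached 15.8% of these genes, below the mean of 27.4% of its random sets, so the high frequency was not shared by the PABPC1 list. That test does not decide whether such genes are open to both immunoprecipitations. It was chosen after its counts had been seen, and a difference in source RNA between the libraries was not excluded. No biological explanation was tested. Reads shared between similar zinc finger genes and the expression level of these genes were not tested either and stay open.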
